A study of Homo sapiens with 4 samples.

How the data were processed

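The series holds 4 Affymetrix exon arrays of MCF7 cells, 2 from cells transfected with an siRNA against RBBP6 and 2 from cells given a nontargeting control siRNA, in each case at 50 nM with material taken after 72 h. Groups and replicate numbers were read from the sample titles. Per the labels' protocols, RNA was purified on columns with DNase treatment, after nuclear extracts had been prepared from the transfected cells, and was labelled with a whole-transcript kit. The labels do not make clear whether the RNA came from whole cells or from those extracts.

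The values used are the deposited log2 signals per probe set. RMA and Affymetrix Power Tools are named in the submitters' processing notes, without versions or settings. The log2 scale was inferred from the values, which ran from 1.56 to 15.1. The median over probe sets was 5.00 and 4.99 on the siRBBP6 arrays and 4.99 and 4.95 on the siCtrl arrays. The exact normalization, the background correction and the genome build are not given in the sources used here, and scanner files were not used here. The arrays have 1 colour, so no direction had to be settled. No detection calls were used, so a dim probe set has no stated limit, and the number of arrays limits the precision. GEO's platform annotation paired 357604 probe sets with 1 gene symbol, 15322 with several and 1038473 with none. Probe sets with several symbols were not named. Symbols are those of the platform and can be old. Of 19560 different symbols, 16472 are current in RefSeq (GRCh38.p14), a table used only for names, synonyms and the order of genes.

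A probe set was used if it had exactly 1 symbol and its mean over the arrays was at or above the median of all probe sets, 4.96. This kept 268398 probe sets, and 265423 of them fell in the 16909 genes with at least 3. The gene value was the median of its used probe sets, with a median of 13 per gene. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, group as the only term), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Probe sets at or above the median were tested in the same way. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the 25 lists. Of 734 list entries, 684 matched a symbol, 82 of them through a synonym. Usage within genes was tested with diffSplice. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for joins, order along chromosomes and figures.

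Genes were named by a rule fixed before the data were examined. It named RBBP6, the genes with the largest changes past the adjusted threshold and, as none passed, the 5 smallest p-values in each direction, with RBBP6 itself among the 5 lower ones. For each list it named up to 4 members with the smallest p, and for usage the 5 genes with the smallest Simes p. The arrays of the 2 groups also had to be separated for the smallest-p genes, which the rule states only for genes past the threshold. Symbols that are LOC, orf or clone names (FLJ, DKFZ, MGC) were not named. RBBP6 was judged as a single planned gene by its unadjusted p. That threshold was not fixed beforehand and was chosen after its adjusted p over all genes had been seen, so both are given.

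Each step was tested on simulated data with variances drawn from the fitted prior. In 16909 simulated genes with 200 changed, the gene fit recovered 37% at a log2 change of 1 and 97% at 2, with 4 false calls. Camera recovered a list shifted by 0.3, estimated at a median of 0.439, with 0 false calls. The simulated genes varied independently of each other. The result therefore does not show how often lists of genes that vary together would pass falsely. In 265423 simulated probe sets with 200 changed, the limma test of single probe sets recovered 9% at a log2 change of 1.5 and 75% at 3, with 7 false calls. For usage, diffSplice recovered 57% of genes with a probe set changed by 1.5 and 100% at 3, with 743 false genes, because it pools the variance over a gene. A test of each probe set against the mean of the gene's other probe sets, with a variance of its own, recovered 13% and 78% with 15 false calls. An earlier form of that test, against the gene's median, recovered nothing and was replaced. The first simulation drew noise from the moderated variances and was replaced by the fitted prior. diffSplice remained the principal usage test because it had been fixed beforehand.

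Alternatives fixed beforehand were the replicate number as a block, each array left out, median centring, quantile normalization, other brightness filters, other gene summaries, other moderation settings and other list tests. A lone array left in a group was assumed to vary like the other group. Array weights, the own-variance usage tests and camera with an estimated correlation and 1 control left out were added after the data were seen. A planned test of AU content in 3' UTRs and a planned test of 3' UTR against upstream probe sets were not run, since no genome with transcripts and no probe set positions were used here.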

Results

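MCF7 cells, an estrogen receptor-positive line derived from a human breast cancer, were transfected with an siRNA against RBBP6 or with a nontargeting control siRNA. RBBP6 is a RING finger protein of the pre-mRNA 3' processing complex that also binds p53 and RB. The siRNA was used at 50 nM and material was taken 72 h after transfection. RNA was measured on 4 exon arrays, 2 for siRBBP6 and 2 for siCtrl. Each array reported 1411399 probe sets, most of which stand for single exons or parts of exons, as log2 signal. The comparison asked which transcripts, and which parts of transcripts, differed between cells with and without the knockdown, with the 3' processing machinery and AU-rich mRNAs named in the series title. No label says that the 2 arrays of a group came from separate cultures, so p-values of the limma fits measure only the spread between these arrays, which may be technical. Camera at the preset correlation compares the genes of a list with the other genes. The Fisher's exact tests further below compare probe sets. The p-values of these 2 tests do not measure the spread between arrays. Over the 16909 genes tested, the siRBBP6 arrays had a Pearson correlation of 0.979 with each other. siCtrl replicate 1 correlated with them at 0.972 and 0.974, whereas siCtrl replicate 2 correlated with siCtrl replicate 1 at 0.955 and with the siRBBP6 arrays at 0.927 and 0.949. These are correlations across genes, which are not independent replicates.

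RBBP6 itself was lower in both siRBBP6 arrays. Its gene value was 8.89 ± 0.0429 (SD, n = 2) on the log2 scale in siRBBP6 and 10.10 ± 0.157 (SD, n = 2) in siCtrl. The log2 fold change was −1.21 with a standard error of 0.176 and a 95% confidence interval of −1.60 to −0.82. That is 43.2% of the control signal, with an interval of 32.9% to 56.7%. The limma p for this single planned gene was 4.84e-05, and its Benjamini-Hochberg adjusted p over all genes was 0.126, which did not pass 0.05. That adjusted p passed when certain arrays were left out, at 0.0382 without siRBBP6 replicate 1, 0.0220 without siRBBP6 replicate 2 and 0.00641 without siCtrl replicate 1, and was 0.125 without siCtrl replicate 2. Of 39 RBBP6 probe sets, 35 were bright enough to be used, and in 29 of these both siRBBP6 arrays lay below both control arrays. The other 6 did not separate in that way. Among them, the neighbouring probe sets 3653336, 3653337 and 3653338 had a median log2 fold change of 0.357, against −0.98 for the other used RBBP6 probe sets. Relative to the rest of the gene, limma's diffSplice gave them adjusted p-values of 0.0102, 0.0786 and 0.0201. A test with a separate variance for each probe set, chosen after the data were seen, gave 0.465, 0.387 and 0.225.

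**Figure D1:**
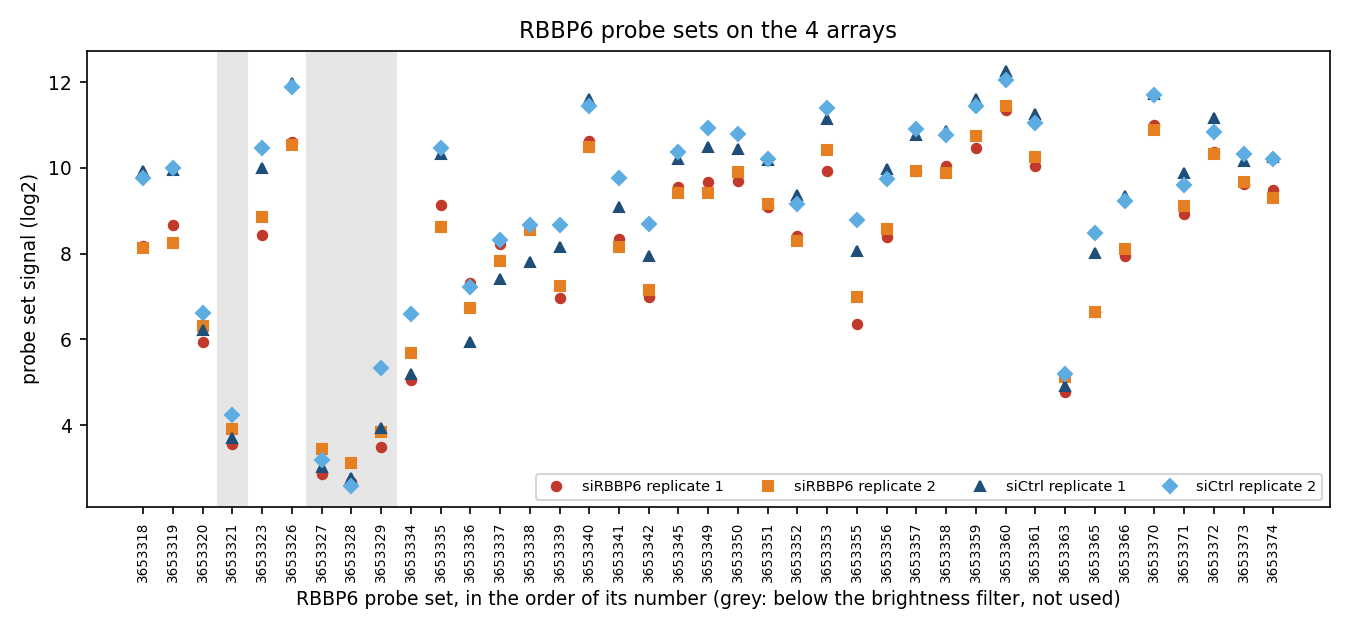
Log2 signal of each of the 39 RBBP6 probe sets (x axis, in the order of their numbers) on the 4 arrays, 1 point per array, with grey bands for the probe sets too dim to be used. In 29 of the 35 used probe sets both siRBBP6 points lie below both siCtrl points, and probe sets 3653336 to 3653338 are among the 6 that do not.

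Among genes other than RBBP6, the lowest p-values for lower signal belonged to TFPI, APOBEC3B, STS and DFFA, and those for higher signal to BDKRB1, SUPT4H1, USP16, APLP2 and SFRS12IP1. None of them passed the adjusted threshold. TFPI, an inhibitor of the tissue factor pathway of coagulation, had a log2 fold change of −2.04 (SE 0.251), with 5.63 ± 0.153 in siRBBP6 and 7.67 ± 0.393 in siCtrl (SD, n = 2 each). Not all of its probe sets fell, as 2591466 was at 6.94 and 7.21 in siRBBP6 against 6.26 and 6.45 in siCtrl. APOBEC3B, a cytidine deaminase with close paralogs whose RNA its probes may also bind, had −1.56 (SE 0.201). STS, the steroid sulfatase, had −1.66 (SE 0.216), and DFFA, the inhibitor of the caspase-activated DNase, had −1.46 (SE 0.209). DFFA probe set 2396134 did not fall, at 9.54 and 9.63 in siRBBP6 against 9.42 and 9.43 in siCtrl. BDKRB1, a bradykinin receptor, had a log2 fold change of 1.36 (SE 0.219) on 4 probe sets. SUPT4H1, a subunit of the elongation factor DSIF, had 0.96 (SE 0.157), and the histone deubiquitinase USP16 had 1.04 (SE 0.190). APLP2, a relative of the amyloid precursor protein, had 1.02 (SE 0.186), and SFRS12IP1, which binds a splicing regulator, had 1.36 (SE 0.249). These 9 genes were chosen among those whose siRBBP6 arrays both lay on the same side of both control arrays.

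With limma over all 16909 genes, 0 genes were higher and 0 lower at an adjusted p under 0.05, and the lowest adjusted p was 0.110. At an unadjusted p under 0.05, 354 genes were higher and 1515 lower, 1869 in all, where 845 would pass by chance alone. At least 2-fold differences among them numbered 24 higher and 167 lower. The groups did not overlap in 40.8% of genes, against 33.3% by chance for 2 arrays against 2. Lower genes made up 81.1% of the unadjusted calls with both controls and 68.7% without siCtrl replicate 2, where 421 were higher and 925 lower. The adjusted count depended on single arrays. It was 3 higher and 24 lower without siRBBP6 replicate 1, 2 and 99 without siRBBP6 replicate 2, 243 and 1308 without siCtrl replicate 1, and 0 and 0 without siCtrl replicate 2.

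**Figure D2:**
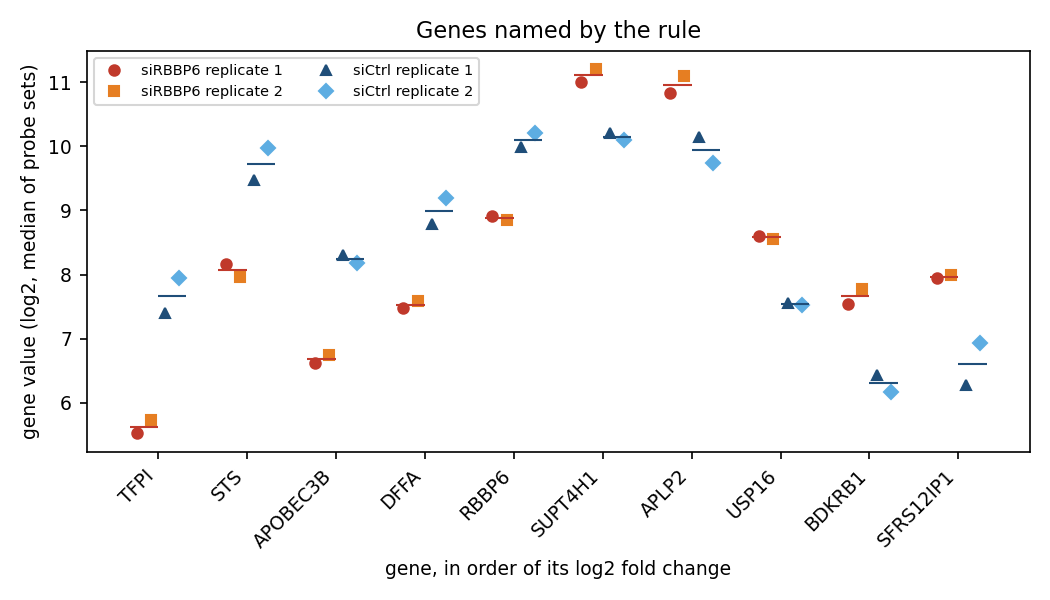
Gene values (y axis, log2, median of the gene's used probe sets) of the 10 genes named by rule on each of the 4 arrays, with short lines at the group means. Separation of the 2 groups was a condition of the choice for the genes other than RBBP6. The genes run from a log2 fold change of −2.04 for TFPI to 1.36 for SFRS12IP1, and none passed the adjusted threshold over all genes.

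Of 25 gene lists, 2 passed camera with the preset correlation, both toward lower signal in siRBBP6. E2F targets and DNA replication genes, which serve S phase, had a median log2 fold change of −0.20 over 42 genes (adjusted p = 0.0128, and adjusted p = 0.917 with an estimated correlation). At an unadjusted p under 0.05, 0 members were higher, 9 lower and 33 did not pass. DTL had −0.84 (SE 0.196), CCNE2 −0.74 (SE 0.186), POLA1 −0.68 (SE 0.197) and CLSPN −0.72 (SE 0.248). The nuclear exosome and its cofactors, which degrade nuclear RNA from the 3' end, had a median of −0.26 over 19 genes (adjusted p = 0.0429, and adjusted p = 0.917 with an estimated correlation). Of these, 0 were higher, 5 lower and 14 did not pass at an unadjusted p under 0.05. MPHOSPH6 had −0.87 (SE 0.227), EXOSC2 −0.46 (SE 0.156), EXOSC5 −0.50 (SE 0.179) and EXOSC8 −0.57 (SE 0.205). No member of either list passed adjusted over all genes, nor adjusted over the list alone. Both calls rested on particular arrays. The E2F list had an adjusted p of 0.640 without siCtrl replicate 1 and 0.202 without siRBBP6 replicate 2, while without siCtrl replicate 2 its median was −0.37 (adjusted p = 2.74e-08, and adjusted p = 0.942 with an estimated correlation). The exosome list had 0.667 without siCtrl replicate 2, 0.199 without siRBBP6 replicate 1 and 0.0794 without siRBBP6 replicate 2, while without siCtrl replicate 1 its median was −0.42 (adjusted p = 0.0180, and adjusted p = 0.9325 with an estimated correlation).

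The other 23 lists did not pass with both controls, and a statement that a gene passed over its list is not one that it passed over all genes, where none did. Among 24 cleavage and polyadenylation factors, 2 were higher adjusted over the list alone. These were NUDT21, a subunit of cleavage factor I, at 1.12 (SE 0.223), and CSTF1, a subunit of the cleavage stimulation factor, at 0.73 (SE 0.176). PCF11 was at 0.52 and CPSF6 at −0.38, and the list had a median of −0.12 (adjusted p = 0.755). Its mean was 0.00209, so mean and median differed in sign. Factors that bind AU-rich elements or remove poly(A) tails had a median of −0.0893 over 29 genes (adjusted p = 0.762). Adjusted over the list alone, ZFP36L1 at 0.84 (SE 0.185) and TOB1 at 0.50 (SE 0.134) were higher and ZFP36L2 at −0.91 (SE 0.236) was lower. ELAVL1 was at 0.60, and at −0.18 under a stricter brightness filter. Immediate-early and AU-rich element mRNAs had a median of −0.11 over 36 genes (adjusted p = 0.717), with 2 higher and 6 lower adjusted over the list alone. FOS, a subunit of AP-1, was at −1.06 (SE 0.220), RND3 at −1.01 (SE 0.242) and SGK1 at −1.12 (SE 0.274). ZFP36L1 at 0.84 and ZFP36L2 at −0.91 belong to this list too. Splicing factors of the SR and hnRNP families had a median of −0.13 over 32 genes (adjusted p = 0.717), with HNRNPU at 8.96 in siRBBP6 and 9.96 in siCtrl and SFRS7 at a log2 fold change of −0.73 (SE 0.190).

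Of genes tied to the receptors and partners of these cells, 27 estrogen receptor targets had a median of 0.0395 (adjusted p = 0.178). Adjusted over the list alone, 3 were higher. They were TFF3 at 1.14 (SE 0.213), the amino acid transporter SLC7A5 at 0.63 (SE 0.122) and RET at 0.76 (SE 0.193), while TFF1 was at 0.36 and did not pass. At an unadjusted p under 0.05, 6 members were higher, 4 lower and 17 did not pass. The lower ones, which the naming rule did not reach, were TPD52L1 at −0.65, ESR1 at −0.40, CTSD at −0.36 and GATA3 at −0.36. Without siCtrl replicate 2 this list had a median of 0.0973 (adjusted p = 0.0223, and adjusted p = 0.942 with an estimated correlation), and without siCtrl replicate 1 it had 0.00487 (adjusted p = 0.435). Luminal epithelial genes had a median of −0.11 over 19 genes (adjusted p = 0.859), with ERBB3 at −1.12 (SE 0.206) lower and TFF3 higher adjusted over the list alone. RB and RBBP family partners had a median of −0.20 over 13 genes (adjusted p = 0.717). RBL2, the RB relative p130, was lower adjusted over the list alone at −1.27 (SE 0.208), and RBBP4 was at −0.50. The 29 p53 target genes had a median of −0.0246 (adjusted p = 0.717), with MDM2 at 0.57, FAS at 0.58, CD82 at 0.57 and PLK2 at −0.84. The direction of that list depended on the control array. Its median was 0.13 without siCtrl replicate 2 (adjusted p = 0.00292, and adjusted p = 0.942 with an estimated correlation) and −0.15 without siCtrl replicate 1 (adjusted p = 0.475). The 19 apoptosis regulators of the BCL2 family had a median of −0.13 (adjusted p = 0.808), with PMAIP1 at −0.87 and BCL2L11 at −0.63.

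Among lists of growth and metabolism, 21 cholesterol synthesis genes had a median of −0.27 (adjusted p = 0.124), and LSS, the lanosterol synthase, was lower adjusted over the list alone at −0.92 (SE 0.177). FDPS was at −0.66. Without siCtrl replicate 1 that list had a median of −0.40 (adjusted p = 0.0337, and adjusted p = 0.9325 with an estimated correlation), and without siCtrl replicate 2 it had −0.0867 (adjusted p = 0.667). The 37 mitosis genes had a median of −0.0354 (adjusted p = 0.717), with AURKA at 0.59, PLK1 at 0.69 and HMMR at −0.59. The direction of the mitosis list also depended on the control array, with a median of 0.20 without siCtrl replicate 1 (adjusted p = 0.0241, and adjusted p = 0.9325 with an estimated correlation) and −0.13 without siCtrl replicate 2 (adjusted p = 0.395). Hypoxia and glycolysis genes had a median of −0.04996 over 25 genes, ribosomal proteins −0.0988 over 69 and oxidative phosphorylation genes −0.0934 over 59, each with an adjusted p of 0.717. ALDOC was at −0.88, EGLN3 at −0.73 and NDUFA2 at −1.15. Replication-dependent histones had a median of −0.11 over 12 measured genes (adjusted p = 0.859), with HIST2H2BE at −1.30. These 12 came from 34 entries that matched a symbol, and further entries of the list matched none. Their near-identical copies leave single members uncertain. Replication-independent histones had −0.0791 over 9 genes (adjusted p = 0.728).

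Stress and interferon lists did not pass either. The integrated stress response had a median of −0.00743 over 25 genes (adjusted p = 0.717), with NUPR1 at 0.75 and ATF5 at −0.55. The unfolded protein response of the endoplasmic reticulum had −0.15 over 22 genes (adjusted p = 0.808), with SEC24D at −0.95. Heat shock and proteotoxic stress genes had −0.0322 over 15 genes (adjusted p = 0.967). Interferon-stimulated genes had −0.0596 over 27 genes (adjusted p = 0.717), and IFI44L was lower adjusted over the list alone at −1.43 (SE 0.273). Markers of other cell types were also measured. The 15 fibroblast and mesenchymal genes had a median of 0.13 (adjusted p = 0.530), with FN1, the fibronectin gene, lower adjusted over the list alone at −1.40 (SE 0.243) and CDH2 at 0.65. The 13 basal epithelial genes had 0.0488 (adjusted p = 0.881), with CDH3 lower adjusted over the list alone at −0.79 (SE 0.158) and ITGA6 at 0.83. The 10 leukocyte genes had 0.0655 (adjusted p = 0.717), and LYZ, at −1.86, had a control SD of 1.98. Median, mean and camera's direction differed in sign for the mitosis, p53, integrated stress response, leukocyte, basal, and cleavage and polyadenylation lists.

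**Figure D3:**
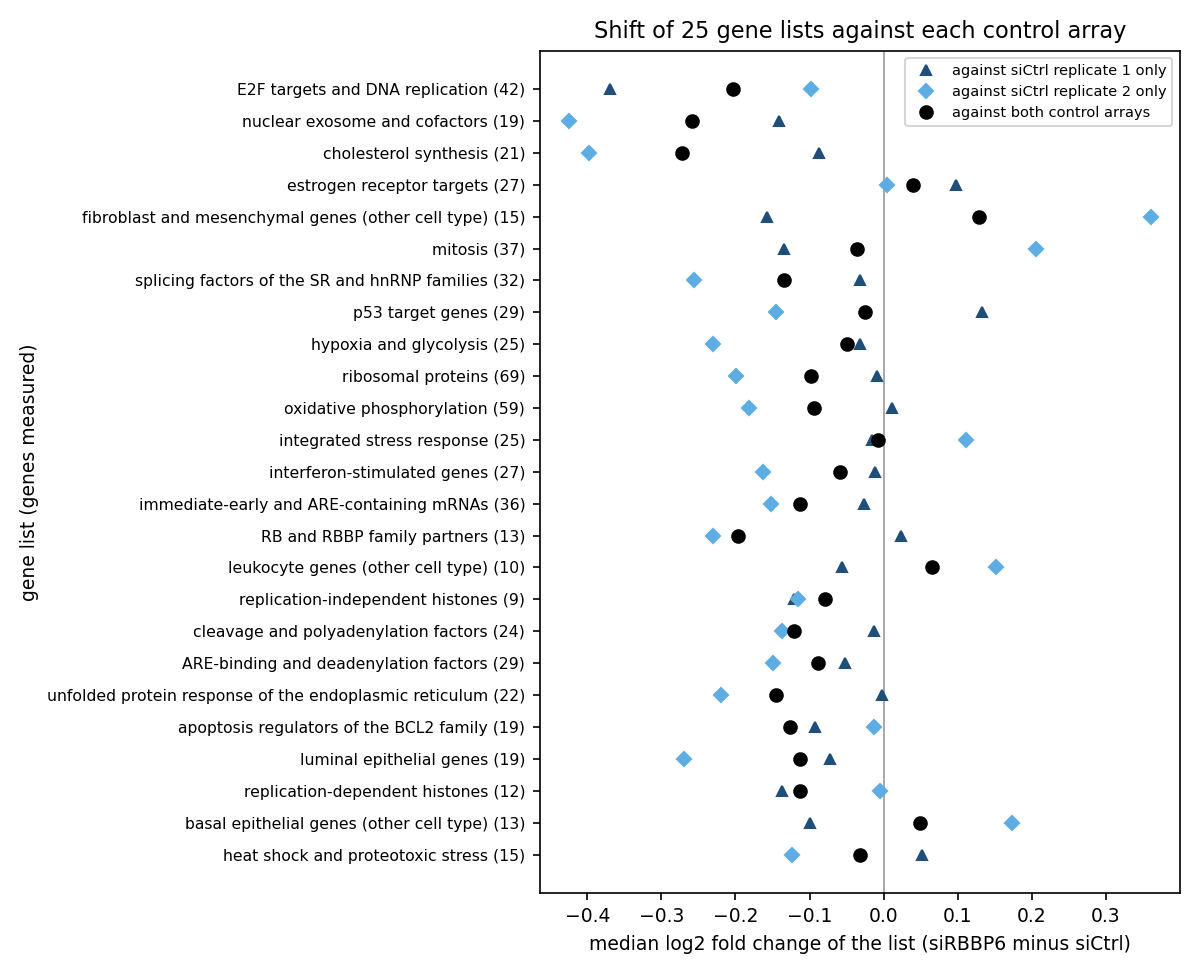
Median log2 fold change (x axis, siRBBP6 minus siCtrl) of the 25 gene lists (y axis, with the number of genes measured), against both control arrays (black circles) and against each control array alone (triangles and diamonds). The E2F list lies at −0.37 against siCtrl replicate 1 and at −0.0976 against siCtrl replicate 2, and the exosome list at −0.14 and −0.42.

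Of 705700 probe sets tested with limma, 0 were higher and 0 lower at an adjusted p under 0.05 (lowest 0.176). In simulated data the same test recovered only 9% of probe sets with a log2 change of 1.5 and 75% at 3, so changes could be missed. At an unadjusted p under 0.05, 18004 of the 705700 were higher and 33424 lower. Of 268398 tested probe sets with 1 gene symbol, 6161 were higher and 24491 lower. Of 426140 tested with no gene symbol given, 11603 were higher and 8094 lower. Chance alone would give a share of 0.05 for both directions combined. Probe sets with 1 symbol exceeded that share, and those with none stayed below it. The adjusted count was 1 higher and 8 lower without siRBBP6 replicate 1, 8 and 97 without siRBBP6 replicate 2, 9554 and 21239 without siCtrl replicate 1, and 134 and 58 without siCtrl replicate 2.

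Probe sets were then compared with the rest of their gene. SF3B3, a splicing factor subunit, HUWE1, a ubiquitin ligase, KIAA0368, the nucleoporin NUP98 and TANC2 had the smallest diffSplice p-values. In SF3B3, probe set 3667329 was at 7.60 and 7.79 in siRBBP6 and at 6.23 and 6.31 in siCtrl, while the gene as a whole had a log2 fold change of −0.0388. In KIAA0368, probe set 3220512 was at 7.46 and 7.57 against 5.66 and 5.54. Probe set 3220516 of that gene went the other way, at 4.48 and 6.28 against 6.34 and 7.70. In NUP98, probe set 3359950 was at 5.60 and 5.32 against 7.35 and 7.11, and in TANC2, probe set 3730525 was at 4.62 and 5.03 against 6.51 and 6.61. HUWE1 probe set 4009316 was at 5.77 and 5.73 against 4.58 and 3.84, with both control arrays below the median of all probe sets. With diffSplice, 439 of 16909 genes passed the Simes test at an adjusted p under 0.05, with 299 probe sets higher and 397 lower relative to their gene. The count carries little weight on its own. In data simulated for this comparison, with a variance for each probe set and 200 altered genes among 16909, the same test called 743 unaltered genes. With a separate variance for each probe set, chosen after that simulation, 0 probe sets passed (lowest adjusted p 0.0963), and 10511 were higher and 9192 lower at an unadjusted p under 0.05. The diffSplice count was 42 without siRBBP6 replicate 1, 166 without siRBBP6 replicate 2, 2820 without siCtrl replicate 1 and 264 without siCtrl replicate 2, and 119 of the last were also called with both controls.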

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

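Array weights, the own-variance usage tests and the estimated correlation with 1 control left out were chosen after the data were seen, and the cause of the differences below was not tested except where stated. RBBP6 stayed lower with an unadjusted p under 0.05 under all 13 alternatives, from −1.32 to −0.92. The replicate numbers are not known to pair the arrays: the replicate differences of the 2 groups correlated at 0.332 across genes, from 2 pairs. With the replicate block, RBBP6 had an adjusted p over all genes of 0.000163, and 139 genes were higher and 943 lower, 715 and 3437 probe sets, and 1090 genes for usage. Array weights gave 9 lower genes. Leaving out 1 array gave 0 to 243 higher and 0 to 1308 lower genes, 1 to 9554 higher and 8 to 21239 lower probe sets, 42 to 2820 usage genes and 0 to 3 lists. The largest gene, probe set and usage counts came without siCtrl replicate 1. The usage count was 665 with no brightness filter, 213 with the filter at the 75th percentile, 227 with the F test, 0 with own variance and 161 with own variance and without siCtrl replicate 2. The number of lists past the threshold was 1 after quantile normalization, 1 with the filter at the 75th percentile, 1 with at least 6 probe sets, 0 with fry and 0 with an estimated correlation, both on all 4 arrays and with either control left out. The directions of lists were taken from camera, so a list can turn while its median keeps its sign.

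No list passed in a setting where its direction turned. The medians of those that turned over the fits without 1 array ranged from −0.136 to 0.0629 for heat shock, −0.200 to −0.0088 for ribosomal proteins, −0.189 to 0.0108 for oxidative phosphorylation, −0.0559 to 0.152 for leukocyte, −0.146 to 0.133 for p53, −0.100 to 0.174 for basal, −0.211 to −0.00707 for cleavage and polyadenylation, −0.137 to −0.00548 for replication-dependent histones, −0.151 to −0.0263 for immediate-early, −0.134 to 0.205 for mitosis, −0.163 to 0.0732 for interferon, −0.220 to −0.00244 for unfolded protein, −0.255 to −0.0317 for splicing, −0.191 to −0.0357 for AU-rich element binding, −0.230 to 0.0228 for RB partners, −0.269 to −0.0182 for luminal and −0.158 to 0.360 for fibroblast genes. For genes, CD4 ranged from −0.0570 to 0.831, H2AFY from −0.726 to 0.0462 and H2AFX from −0.135 to 0.454. p53 passed without siCtrl replicate 2 at the preset correlation, but not with an estimated correlation. Its camera direction was up there and with both controls, although its median with both controls was −0.0246. Heat shock was at −0.0218 after quantile normalization, −0.0301 with no filter, −0.0507 at the 75th percentile, −0.00451 with the mean of probe sets and −0.0486 with at least 6 probe sets. With no filter, luminal genes were at −0.114, leukocyte genes at −0.0420, COL3A1 at −0.0222, RPL28 at 0.0823, CD4 at −0.0287 and HIST1H2BJ at −0.393. At the 75th percentile, immediate-early genes were at −0.0822, apoptosis regulators at 0.0429 and ELAVL1 at −0.175. With the mean of probe sets, immediate-early genes were at −0.0230, replication-independent histones at −0.0136, RPS23 at −0.0701, MTHFD2 at −0.0292 and HIST1H2BJ at −0.0411. With median polish, immediate-early genes were at 0.0307, apoptosis regulators at 0.0326, HNRPDL at −0.0448, RPS23 at −0.00129 and HIST1H2BJ at −0.121. With fry, cleavage and polyadenylation factors were at −0.121 and the integrated stress response at −0.00743. With an estimated correlation and without siCtrl replicate 2, interferon genes were at −0.0121, heat shock at 0.0522, AU-rich element binding at −0.0527 and luminal genes at −0.0729. The correlation does not change a list's median, so all lists had the medians of the fit without that array. In all, 53 of 424 list values and 14 of 1747 gene values turned, and 348 and 1598 kept direction and side. The planned tests of AU content and of 3' UTR against upstream probe sets, with their alternatives, were not run. Dim probe sets near the median of 4.96 limit what can be read from small shifts.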

Other observations

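Tests of the 3 RBBP6 probe sets, of the other groupings of the arrays and of the usage positions in those groupings were chosen only after the results were seen. The same holds for the probe sets and genes named in the rest of this paragraph. Single probe sets outside the named genes showed large differences, none past the adjusted threshold (lowest adjusted p 0.176). A run of unnamed probe sets, 3341044 to 3341049, had log2 fold changes of 2.52 to 3.33. Probe set 3341046 was at 10.3 and 10.0 in siRBBP6 and at 7.15 and 6.56 in siCtrl. The numbers of the run lie between those of TSKU and ACER3. The 4 TSKU probe sets nearest to the run differed by 0.58 to 0.85, and the unnamed probe set 3341041 next to them by 0.25. H19, a long noncoding RNA, had probe sets at 1.75 and 1.88. Others were lower, with SLCO4C1 probe set 2869099 at −2.74, RAB26 probe set 3644518 at −2.24 and DGAT1 probe sets at −1.90 and −1.95. In HNRNPD, an AU-rich element binding protein, probe set 2775465 was at 10.8 and 10.7 against 9.09 and 8.98. The unnamed probe sets that follow HNRNPD in the inferred 3' direction averaged 6.76 and 7.06 in siRBBP6 against 4.96 and 4.91 in siCtrl. Those siCtrl values lay at about the brightness cut of 4.96, so the size of this difference is uncertain.

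The 3 neighbouring RBBP6 probe sets did not fall with the rest of the gene. For the 2 brighter of them, compression of dim probe sets is argued against by the 7 dimmer used RBBP6 probe sets, whose median log2 fold change was −1.23 (SD 0.662) and 4 of which fell by 1.23 to 1.74, while for the dimmest it stays open, since the 3 still dimmer probe sets had a median of only −0.28 with overlapping groups. Without siCtrl replicate 2 the mean usage shift of the 3 was 1.68 (SD 0.235), above the 1.28 with both controls. The 3 had been picked by a fold change above 0 on these same arrays. They were at 5.95, 7.41 and 7.81 in siCtrl replicate 1 and at 7.22, 8.31 and 8.66 in siCtrl replicate 2. Their fold changes above 0 thus rest on siCtrl replicate 1, and leaving out siCtrl replicate 2 could only raise the shift. This test cannot decide about single control arrays. A short RBBP6 RNA that the siRNA does not lower is a candidate explanation that stays open, because probe set positions and transcripts were not used here. The own-variance test did not call the 3 probe sets, so the pattern itself is uncertain.

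More genes were lower than higher at an unadjusted p under 0.05, with 81.1% lower. The median log2 fold change over all genes varied with brightness. It was 0.0517 for gene means under 6, 0.0175 at 6 to 7 and −0.0551 at 7 to 8. For brighter genes it was −0.105 at 8 to 9, −0.102 at 9 to 10 and −0.0492 from 10 up. Whether this trend accounts for the excess of lower genes was not tested. After quantile normalization the share was 76.7%. The deposited arrays already had nearly equal distributions, with 75th percentiles from 6.8236 (siCtrl replicate 2) to 6.8449 (siCtrl replicate 1). Quantile normalization could therefore change little, and the test cannot decide about scaling between arrays. siCtrl replicate 2 cannot be told apart from the knockdown as a source, because without it the share was 68.7%, between the bounds of 60% and 70% set before the value was seen. Of the 3 ways to split 4 arrays into pairs, 1 gave as many genes, the real one with 1869, and the highest other, which separates the replicate numbers, gave 867. With 3 splits no share under 0.05 can be reached.

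Unnamed probe sets after the inferred 3' end of genes were higher relative to their gene in siRBBP6, by a median of 0.154 over 9936 genes. The shift was 0.102 against siCtrl replicate 1 alone and 0.209 against siCtrl replicate 2 alone, but the arrays of 1 group differed by 0.117 (siRBBP6) and 0.112 (siCtrl), so a role of siCtrl replicate 2 stays open. Background outside genes may account for it, since probe sets before the 5' end shifted by 0.150. Tested probe sets with no symbol had a median log2 fold change of 0.0883 as a whole, against −0.0576 for those with 1 symbol. A shift of this kind was thus not limited to the 3' end. The median difference between the ends was 0.0145 (95% interval over genes 0.002 to 0.0244), which met the bound written beforehand against background, as the 0.102 met the one against siCtrl replicate 2. Both verdicts were changed to undecided after the values were seen, because that interval leaves out the spread between arrays, and the difference was 0.0325 (0.022 to 0.0415) against siCtrl replicate 1 alone but −0.0088 (−0.0257 to 0.0068) against siCtrl replicate 2 alone, so longer 3' ends or read-through after the knockdown stay open too.

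A hypothesis was that probe sets with raised usage lie at the 3' end of their gene. Among diffSplice calls on genes with an inferred direction, 74 of 232 higher probe sets (31.9%) were the last or last but one, against 23 of 287 lower ones (8.01%) and 11.8% of all tested (Fisher's exact test, two-sided, p = 3.13e-12, adjusted 3.13e-11 over the 10 position tests run). Without siCtrl replicate 2 the counts were 67 of 206 and 3 of 80 (adjusted p = 1.51e-07, Fisher's exact test). This fits the hypothesis for those calls, and other values limit it. Own-variance calls without siCtrl replicate 2 gave 27 of 118 against 0 of 16 (adjusted p = 0.0824, Fisher's exact test), and 27.1% of the higher ones lay at the 5' end, more than the 22.9% at the 3' end. The split by replicate number, which has 1 array of each treatment on either side, had its own excess at the 5' end, with 11 of 43 against 7 of 142 (adjusted p = 0.00103, Fisher's exact test). Over all 12596 genes with a direction, the shift of the last named probe set minus that of the first had a median of −0.0757 with both controls and of 0.0358 against siCtrl replicate 1 alone. Probe sets of 1 gene are not independent, and the directions come from the order of probe set numbers, not from positions. The usage count of 439 genes was reached by 1 of the 3 splits, the real one, with 229 in the highest other, and 3 splits are too few for a share under 0.05. The hypothesis may therefore describe diffSplice's calls rather than the cells.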
